A study of Homo sapiens with 66 samples.

How the data were processed

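RNA was measured by sequencing in 66 libraries of HCT116, a human colorectal carcinoma cell line, from wild-type cells and from 6 knockout lines. Cells had been given tunicamycin, an inhibitor of N-linked glycosylation that causes misfolded protein to build up in the endoplasmic reticulum (ER), at 0.5 µg/ml for 6 h, or 0.1% DMSO, the solvent. The libraries formed 22 groups of 3 biological replicates in 5 experimental sets. Each set held its own wild-type (WT) libraries with and without tunicamycin. The knockout lines ATF4_KO, ATF6_KO and XBP1_KO were in set 2, CHOP_KO (gene DDIT3) in set 3, CEBPB_KO in set 4 and NFIL3_KO in set 5.

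Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.6.0c, RSEM 1.3.1, SAMtools 1.3.1 and deepTools 3.4.3 were used with the human genome build hg19. The role of each tool was not stated. The deposited tables held, per the file headers, RSEM expected counts, TPM (transcript counts scaled to length and library) and FPKM (fragments scaled to length and library) for each gene. The expected counts were not whole numbers for 22.99% to 28.62% of the genes with counts in a library, and they were rounded before testing. The TPM were used in 1 alternative and the FPKM in none. Of the 57820 gene identifiers, 51996 matched a symbol in the gene table, and those that did not carried 0.79% to 0.97% of a library's counts. The gene table follows another genome build than hg19, so no coordinates are given. The library kit was NEBNext Ultra, and its strandedness was not stated.

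The total of expected counts per library ran from 20887679 to 36360835. Replicates differed by more than counting error: the chi-square per degree of freedom between a pair of replicates ran from 1.83 to 80.87. A value above 15 against both other replicates set 5 libraries apart, a limit chosen after the data were seen. They were ATF4_KO tunicamycin replicate 1, ATF6_KO tunicamycin replicate 3, XBP1_KO DMSO replicate 2, WT DMSO replicate 1 of set 2 and WT DMSO replicate 2 of set 5. Mitochondrially encoded genes took 3.13% to 9.26% of the counts of a library.

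Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization) in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15. P-values were adjusted over all genes tested in a comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The WT response was fitted on the 30 WT libraries with set as a term. The difference of that response between sets was tested with the interaction of set and treatment. Each knockout line was fitted with the WT libraries of its own set, 12 libraries in all, in 4 groups. The knockout effect on the tunicamycin response was the interaction, that is, the response of the knockout line minus that of WT on the log2 scale. The responses of the 3 knockout lines of set 2 were also compared with each other, which uses no WT library. Log2 values are given ± SE of the fit, and CPM (counts scaled to the library) as mean ± SD.

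The tunicamycin-induced genes were those with a log2 change of at least 1 and an adjusted p under 0.05 in the WT libraries of the other sets, so that they were not chosen on the WT libraries they were then measured against. Their median interaction was set beside the SD between replicate libraries of the median log2 CPM of these genes. That SD describes levels of single libraries and is not the spread of the median interaction. The 29 gene lists held 525 genes, of which 523 were found. They covered UPR (unfolded protein response) sensors and transcription factors, ER chaperones and folding enzymes, ER-associated degradation, ER translocation and signal peptide processing, ER to Golgi transport, N-glycosylation and hexosamine synthesis, stress effectors of the integrated stress response, amino acid and one-carbon synthesis, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, apoptosis regulators, substrates of IRE1-dependent decay, cholesterol synthesis and uptake, cell division, G1/S and DNA replication, p53 targets, type I interferon response, NF-kB and inflammatory cytokine genes, immediate early genes, circadian clock and D-box genes, heat shock response, NRF2 targets, hypoxia response, autophagy and lysosome, colon epithelial identity, mesenchymal markers, markers of blood, endothelium, liver and nerve, mitochondrially encoded genes, and cytosolic ribosomal proteins. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. List p-values were adjusted over the 29 lists of a comparison. The deleted gene was left out of the lists of its own line.

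The comparisons, lists, thresholds and alternatives, and the rule for the genes named in the text, were fixed before the data were examined. The rule took the 6 targeted genes in every comparison. For the WT response it took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, a symbol and the same direction in all 5 sets. For an interaction it took the 6 largest in each direction and the 6 most negative among the induced genes, and for DMSO and knockout against knockout the 5 largest in each direction. Of each list it took up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. The text may name fewer. For genes near 0 CPM in 1 group the CPM are given, either in place of a fold or beside it.

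The alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, no filter on low counts, limma-trend on log2(TPM + 1), the replicate number as a block, 1 fit of all 24 libraries of set 2, other choices of the induced genes, each set left out, the mean of the set contrasts, and each library left out in turn. A run without the libraries that stand apart was added after the data were seen. The other splits of the libraries were counted as a check on grouping. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

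The pipeline was tested on simulated data with 100 genes changed by each fold. It called 88% of the genes changed 1.5-fold and 97% of those changed 2-fold in the WT response, and 63% and 92% in the test between sets. For the interactions the share at 1.5-fold was 48% for ATF4_KO, 47% for ATF6_KO, 34% for XBP1_KO, 66% for CHOP_KO, 59% for CEBPB_KO and 77% for NFIL3_KO. At 2-fold it was 81%, 87%, 80%, 89%, 88% and 85% in that order. Between knockout lines it was 30% and 73% for ATF4_KO against ATF6_KO, 17% and 62% for ATF4_KO against XBP1_KO, and 26% and 76% for ATF6_KO against XBP1_KO. In a comparison of 3 libraries against 3 it ran from 33% to 51% at 1.5-fold and from 73% to 86% at 2-fold. The simulated spread was estimated from the real counts with the tested effect left out of the model, so real effects counted as spread. The shares therefore partly reflect how large the real effect was, and they do not rank the comparisons or lines by power.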

Results

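HCT116 colorectal carcinoma cells with 1 transcription factor of the ER stress response deleted were compared with wild-type (WT) cells, with and without tunicamycin, which blocks N-linked glycosylation. The 66 RNA libraries formed 22 groups of 3 biological replicates. There were 15 WT libraries per treatment over 5 sets, and 3 libraries per treatment of each of 6 knockout lines. The total of expected counts ran from 20887679 to 36360835 per library. Genes are named by the symbol that matched the identifier in the files, and the build was hg19. Unless another test is named, adjusted p-values are from edgeR with the Benjamini-Hochberg method, n = 3 libraries per group, and a gene rose or fell only where its adjusted p was under 0.05. A lower or higher response is the signed log2 difference of responses, so for a gene that fell in WT a higher response can be a weaker fall. Each factor was deleted in 1 line, and the replicates are libraries of that line. SE and p-values thus do not measure how far a knockout effect repeats in another line. Effects of the deleted factor and of the line cannot be told apart, in the interactions as in DMSO.

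The WT libraries asked which genes tunicamycin changed within 6 h. SE and p-values of this response take the library, not the set, as the unit, so they do not measure how far it repeats between sets. DDIT3, which encodes the stress transcription factor CHOP, rose by 5.25 ± 0.07 (log2; adjusted p = 7.42e-35, edgeR, Benjamini-Hochberg). HSPA5, the main Hsp70 chaperone of the ER lumen, rose by 3.63 ± 0.03 (adjusted p = 4.08e-39, edgeR, Benjamini-Hochberg), from 886 ± 76.9 to 11000 ± 1405 CPM (n = 15 each). HERPUD1, a membrane protein of ER-associated degradation, rose by 4.39, and the glutathione-degrading enzyme CHAC1 by 4.34. The other named rises were LURAP1L at 5.19, the mTORC1 inhibitor DDIT4 at 3.56, the leucine sensor SESN2 at 3.55 and the pseudokinase TRIB3 at 3.28. HSPA1B, a stress-inducible cytosolic Hsp70, fell to a log2 change of -2.63 ± 0.05, and AXIN2, a target and negative regulator of Wnt signalling, to -2.31 ± 0.08. GPRC5B, KCNJ12, MAP1A, LFNG, VWA1 and LRFN1 lay between -2.22 and -1.75.

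All 18 measured ER chaperones and folding enzymes rose, with a median log2 change of 2.03 (camera adjusted p = 5.02e-80). Among them were DNAJB9 at 3.20, DNAJC3 at 2.79 and HYOU1 at 2.71. All 14 stress effectors of the integrated stress response rose (median 2.68, camera adjusted p = 5e-45). Of the 16 genes of ER-associated degradation 13 rose and 1 fell (camera adjusted p = 1.99e-28), with the adaptor SEL1L at 2.92 and the ubiquitin ligase SYVN1 at 2.72. Of the 14 UPR sensors and transcription factors 13 rose and 1 fell (camera adjusted p = 1.99e-28), and EIF2AK3, which encodes the sensor kinase PERK, rose by 2.43. The other targeted genes rose too, by 1.88 for CEBPB, 1.56 for NFIL3, 1.52 for XBP1, 1.18 for ATF6 and 1.17 for ATF4.

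Genes that feed amino acids into translation rose together. Of 13 genes of amino acid and one-carbon synthesis 12 rose (camera adjusted p = 3.21e-37), with the aspartate aminotransferase GOT1 at 2.29 and asparagine synthetase ASNS at 2.13. Of 12 amino acid transporters 11 rose and 1 fell (camera adjusted p = 1.19e-20), with the cystine transporter SLC7A11 at 3.03. Of 20 aminoacyl-tRNA synthetases 16 rose and 1 fell (camera adjusted p = 1.63e-22), with WARS1 at 1.74. In the secretory pathway 21 of 23 genes of ER to Golgi transport, 19 of 20 of ER translocation and 20 of 25 of N-glycosylation rose (camera adjusted p = 1.14e-17, 1.2e-15 and 5.74e-11). GFPT1, the entry enzyme of hexosamine synthesis, rose by 1.98. Autophagy genes rose in 14 of 18 cases and fell in 3 (camera adjusted p = 7.72e-05), with MAP1LC3B at 2.63.

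The heat shock list moved the other way: 12 of 13 members fell and none rose (camera adjusted p = 3.1e-10). HSPA8, the constitutive cytosolic Hsp70, had a log2 change of -1.71. Of 7 substrates of IRE1-dependent decay, RNAs cleaved by the ER sensor IRE1, 5 fell and 1 rose (camera adjusted p = 1.53e-04), with TGOLN2 at -1.34. The WT list calls named so far held with an estimated correlation. Other calls did not. Of 17 immediate early genes 13 rose and 2 fell (camera adjusted p = 2.99e-06), with adjusted p = 0.105 with an estimated correlation. Of 17 NRF2 targets 10 rose and 2 fell (camera adjusted p = 0.0331), with adjusted p = 0.334 with an estimated correlation. Of 17 circadian genes 10 rose and 5 fell (camera adjusted p = 0.0458), with adjusted p = 0.273 with an estimated correlation. Of 20 apoptosis regulators 10 rose and 8 fell, with a median of 0.099 that became -0.005 on TPM (camera adjusted p = 0.0402), and adjusted p = 0.13 with an estimated correlation. The counts of called members in the WT response were the same adjusted over the list alone.

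The remaining lists were not called by camera in the WT response. Of 22 genes of G1/S and DNA replication 15 fell and 4 rose (camera adjusted p = 0.139), with the cyclin CCNE1 at -0.92 and the replication licensing factor CDC6 at 1.39. Ribosomal proteins rose in 20 of 24 cases (0.0739), and NF-kB and inflammatory cytokine genes in 10 of 14, with 4 lower (0.157). Cholesterol genes were divided, 8 higher and 10 lower of 24 (0.761), with the sterol carrier STARD4 at 1.79 and the sterol sensor partner INSIG1 at -1.31. Hypoxia genes had 9 of 18 higher and 8 lower (0.368), p53 targets 6 of 17 higher and 8 lower (0.768), and interferon genes 5 of 20 higher and 7 lower (0.932). Cell division genes had 10 of 20 higher and 8 lower, with a median of 0.046 that was -0.07 on TPM (0.954). Colon epithelial genes had 4 of 11 higher and 3 lower, with a median of 0.051 that was -0.042 on TPM (0.936). Mesenchymal markers had 4 of 9 higher and 2 lower (0.885), markers of blood, endothelium, liver and nerve 4 of 7 higher and 1 lower (0.761), and mitochondrially encoded genes 7 of 13 higher (0.668). The values in brackets are camera adjusted p-values.

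edgeR with the Benjamini-Hochberg method called 11503 of 17008 genes in the WT response, 5697 higher and 5806 lower, and on TPM the split was 3628 higher and 7299 lower. At least 2-fold changes were called in 726 genes upward and 385 downward. Of the 11503 genes, 9390 (81.6%) had the same direction in all 5 sets, as had 1062 of the 1111 genes changed at least 2-fold. The genes were called on these same libraries, so part of this agreement was built in and it is not an independent check. The contrasts of single sets, in 1 fit of all WT libraries, called 9021, 6869, 7561, 8396 and 8564 genes, from set 1 to set 5. On TPM the higher share moved by more than 10 points in sets 1 to 4, to 22.4%, 27.7%, 37.2% and 37.8%. The size of the response differed between sets for 4350 genes, among them 475 of the 2-fold genes. SESN2 ranged from 2.89 in set 3 to 4.14 in set 5, and DDIT4 from 2.52 in set 1 to 4.48 in set 4.

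**Figure D1:**
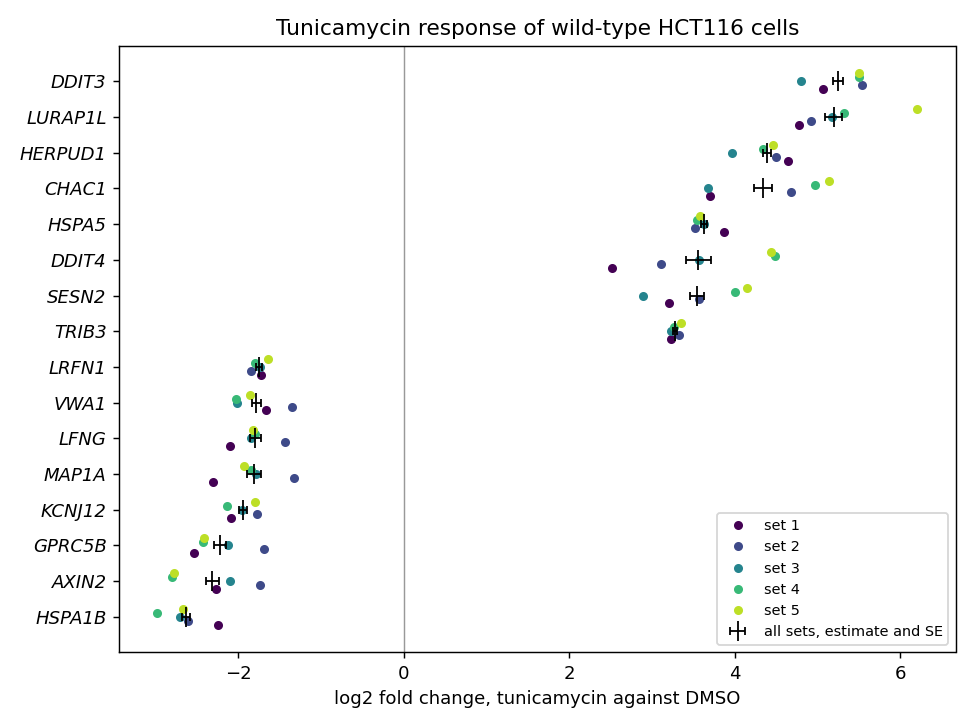
Log2 fold change of tunicamycin against DMSO in WT cells for the 16 named genes. Coloured points are the 5 sets, and black marks are the estimate over all sets with its SE; DDIT3 stood at 5.25 and HSPA1B at -2.63.

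The targeted genes were measured first in each knockout line. ATF4 RNA was 339 ± 14.6 CPM in WT with DMSO and 680 ± 17.4 with tunicamycin, against 40.2 ± 1.12 and 37.3 ± 1.76 in ATF4_KO. ATF6, the membrane-bound sensor and transcription factor, went from 46.7 to 85.9 CPM in WT and stood at 0.231 and 0.22 in ATF6_KO. XBP1, whose RNA is spliced by IRE1, went from 59.1 to 173 CPM in WT and from 0.576 to 2.98 in XBP1_KO. DDIT3 went from 23.7 to 623 CPM in WT of set 3 and from 0.582 to 2.49 in CHOP_KO. NFIL3, a repressor that binds D-box DNA elements, went from 18.8 to 60.8 CPM in WT and stood at 0.0339 and 0.115 in NFIL3_KO. CEBPB, a C/EBP family transcription factor, went from 35.3 to 133 CPM in WT, and in CEBPB_KO from 4.24 ± 0.164 to 47.3 ± 0.761. The RNA of the targeted CEBPB thus still rose, by 3.60 ± 0.06 on the log2 scale, which was 1.57 ± 0.08 more than in WT (adjusted p = 8.08e-09, edgeR, Benjamini-Hochberg). The kind of edit was not stated, so whether this RNA can be translated is not known. Each knockout library was below each WT library of its set and treatment for its own gene.

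**Figure D2:**
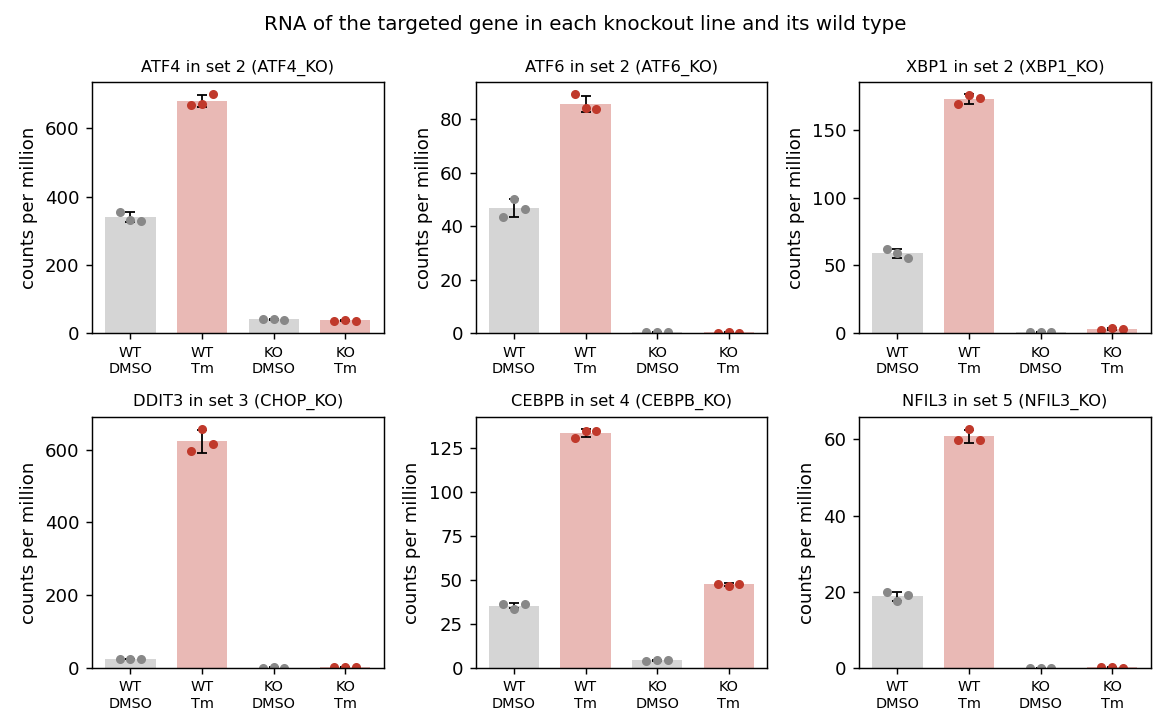
CPM of each targeted gene in the WT and knockout libraries of its set, in DMSO (grey) and tunicamycin (Tm, red). Points are libraries and bars are means ± SD of 3; CEBPB in CEBPB_KO with tunicamycin stood at 47.3 and the other deleted genes at 40.2 or below.

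For ATF4, the transcription factor translated when eIF2alpha is phosphorylated, the question was which part of the response differed in the line without it. In ATF4_KO the response of CHAC1 was lower by -4.83 ± 0.46 (log2 interaction, adjusted p = 1.22e-05, edgeR, Benjamini-Hochberg), from 0.32 to 0.3 CPM against 3.14 to 80.2 in WT. That of SESN2 was lower by -3.60 ± 0.11 and that of TRIB3 by -3.24 ± 0.07. DDIT4 had -2.88, the glycine transporter SLC6A9 -2.58 and the AP-1 family repressor JDP2 -2.54. Of the 13 stress effectors measured, 12 had a lower response, also adjusted over the list alone (median -2.24, camera adjusted p = 1.55e-135). Of 13 genes of amino acid and one-carbon synthesis 12 were lower by both adjustments (camera adjusted p = 6.44e-79), with the serine synthesis enzyme PSAT1 at -2.11, ASNS at -2.01 and GOT1 at -1.84.

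Of 12 amino acid transporters 10 had a lower response in ATF4_KO, 11 adjusted over the list alone (camera adjusted p = 1.37e-40), with SLC1A4 at -2.53 and SLC7A11 at -1.98. Of 20 aminoacyl-tRNA synthetases 12 did, 13 over the list alone (camera adjusted p = 3.21e-20), with CARS1 at -1.16. Of 12 UPR sensors and transcription factors 6 did, 7 over the list alone (camera adjusted p = 5.61e-11): CEBPB had -1.38, NFIL3 -1.36, DDIT3 -1.10 and ATF6 -0.94, each called, and XBP1 -0.15 (adjusted p = 0.384), which was called at -0.25 without ATF4_KO tunicamycin replicate 1 and at -0.28 without the libraries that stand apart. Of 18 chaperones 11 were lower, 13 over the list alone (median -0.312, camera adjusted p = 7.03e-11), with HSPA5 at -0.84. Lower calls were also made for 10 of 20 genes of ER translocation, 14 over the list alone (camera adjusted p = 1.79e-07), and 8 of 16 of ER-associated degradation against 1 higher, 9 over the list alone (camera adjusted p = 1.59e-06).

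For 4 lists the median of ATF4_KO turned positive on TPM: N-glycosylation with 10 of 25 lower (-0.189, and 0.038 on TPM), autophagy with 4 of 18 lower and 1 higher (-0.135 and 0.07), NRF2 targets with 6 of 17 lower (-0.211 and 0.003), and apoptosis regulators with 7 of 20 lower and 3 higher (-0.077 and 0.098). Over the list alone the lower calls were 11, 4, 9 and 8. Among them were GFPT1 at -0.80, MAP1LC3B at -2.11, the glutathione synthesis enzyme GCLC at -0.65 and the death receptor TNFRSF10B at -1.77. The camera calls of the lists so far held with an estimated correlation. ER to Golgi transport had 9 of 23 lower, 15 lower and 1 higher over the list alone, with adjusted p = 0.215 with an estimated correlation. Ribosomal proteins had 8 of 24 lower, 10 over the list alone, with adjusted p = 0.513 with an estimated correlation.

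edgeR with the Benjamini-Hochberg method called 1833 of 16204 interactions in ATF4_KO, 917 higher and 916 lower, of which 26 and 166 were at least 2-fold. On TPM the split was 1720 higher and 361 lower, and the median of all genes moved by 0.147. The response itself was called for 4077 genes in ATF4_KO, 2167 higher and 1910 lower, and on TPM 1817 and 749. Over 677 induced genes the median log2 change was 1.19 in WT and 0.52 in ATF4_KO. The median interaction was -0.625 (SD between libraries 0.021), with 312 genes lower and 5 higher. On TPM this median was nearer to 0, and it moved with the choice of induced genes, with values given below. WNT9A, a Wnt ligand, had a higher response by 1.12, IFFO2 by 1.10, the GATA factor GATA2 by 1.00 and SP6 by 0.97, and all 4 fell in WT. Without ATF4_KO tunicamycin replicate 1, which stood apart, 2969 interactions were called.

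In DMSO, 4967 genes differed between ATF4_KO and WT, 2478 higher and 2489 lower, and on TPM 812 and 2335. NRP1, a co-receptor of semaphorins and VEGF, was 65.2 ± 1.01 CPM in ATF4_KO and 3.76 ± 0.44 in WT (log2 4.12, adjusted p = 2.3e-13, edgeR, Benjamini-Hochberg). LAMA4, ZNF804A, CPA4 and S100A14 were higher by 2.48, 2.15, 2.07 and 1.92. The chloride channel protein CLIC4 was lower at -3.50, TRIB2 at -3.46 and the transcription factor SOX4 at -3.31, and the glutamate receptor gene GRIN2B was 0.0352 CPM against 25.9. The serine synthesis enzyme PHGDH was lower at -2.03 and ASNS at -1.60. Of 13 genes of amino acid synthesis 9 were lower and 1 higher (camera adjusted p = 3.08e-17), of 20 synthetases 10 lower and 3 higher (1.21e-12), and of 13 stress effectors 9 lower and 2 higher (1.38e-11). Of 17 NRF2 targets 12 were higher (camera adjusted p = 9.19e-09). Of 8 mesenchymal markers 5 were lower and 1 higher (camera adjusted p = 3.69e-04), with the intermediate filament gene VIM at 0.299 CPM against 5.82. ER translocation had 13 of 20 genes higher (camera adjusted p = 1.72e-05), N-glycosylation 13 of 25 higher and 1 lower (0.00146), and immediate early genes 8 of 17 higher and 1 lower (0.00465). Those calls held with an estimated correlation, and hypoxia genes, with 11 of 18 lower, had adjusted p = 0.0695 with an estimated correlation. Over the list alone the counts were alike except 11 synthetases lower, 1 NRF2 target lower, 14 translocation and 14 N-glycosylation genes higher and 14 hypoxia genes lower.

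ATF6_KO asked which part of the response differed in the line without the transcription factor cleaved from ATF6. SEL1L rose from 75.2 to 123 CPM in ATF6_KO and from 71.9 to 465 in WT, an interaction of -1.98 ± 0.11 (adjusted p = 5.4e-07, edgeR, Benjamini-Hochberg). HERPUD1 had -1.58 ± 0.07, the chaperone partner SDF2L1 -1.55 and CRELD2, a chaperone of folding, -1.27. TMEM50B had -1.78, FAM222A -1.70 and CRELD1 -1.40. Of 18 chaperones 15 had a lower response, 17 adjusted over the list alone (median -0.898, camera adjusted p = 2.54e-91), among them HSP90B1, the ER Hsp90, at -1.19. Of 16 genes of ER-associated degradation 8 were lower, 12 over the list alone (camera adjusted p = 2.51e-38), with SYVN1 at -0.98 and the mannosidase-like EDEM1 at -0.85.

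Other genes had a higher response in ATF6_KO. Of 17 immediate early genes, which growth factor signals induce, 12 had a higher response, 15 over the list alone (median 0.624, camera adjusted p = 1.68e-31), with EGR3 at 1.83, JUN at 1.18 and EGR1 at 1.11. DDIT4 had 1.63 ± 0.13, ARRDC4 1.49 and the glucocorticoid-inducible TSC22D3 1.21. Of 14 stress effectors 7 had a higher response, 9 higher and 1 lower over the list alone, with adjusted p = 0.0516 with an estimated correlation. NFIL3 had 0.49 and ATF4 -0.33, both called, whereas CEBPB had 0.52, XBP1 0.19 and DDIT3 -0.03, none of them called. An interaction near 0 does not mean equal levels. DDIT3 stood at 5.17 CPM in ATF6_KO and 8.08 in WT with DMSO, and at 228.8 ± 2.48 and 348.3 ± 12.2 with tunicamycin. The call of NFIL3 ended without any 1 of 8 single libraries, and that of ATF4 without any 1 of 6, on TPM and in the fit on all 24 libraries of set 2. CEBPB was called with no filter (0.49), without ATF6_KO tunicamycin replicate 1 (0.66) or 3 (0.31), and without the libraries that stand apart (0.29).

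N-glycosylation had 9 of 25 genes lower in the response of ATF6_KO, 14 over the list alone (camera adjusted p = 6.86e-10). Cholesterol synthesis had 5 of 24 lower, 9 lower and 1 higher over the list alone (camera adjusted p = 5.74e-08), with the HMG-CoA synthase HMGCS1 at -0.77. Heat shock genes had 4 of 13 lower, 5 over the list alone (camera adjusted p = 3e-07), with a median of -0.085 that became 0.003 on TPM. These calls and those of chaperones, ER-associated degradation and immediate early genes held with an estimated correlation. ER to Golgi transport had 4 of 23 lower, 16 over the list alone, and adjusted p = 0.132 with an estimated correlation. ER translocation had 5 of 20 lower, 9 over the list alone, with a median of -0.195 that was 0.004 on TPM, and adjusted p = 0.0516 with an estimated correlation. Cell division had 2 of 20 lower by both adjustments, and adjusted p = 0.0516 with an estimated correlation.

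edgeR with the Benjamini-Hochberg method called 530 of 16213 interactions in ATF6_KO, 273 higher and 257 lower. The split was 190 higher and 65 lower on TPM, where the median of all genes moved by 0.108, and 296 and 486 with no filter. The response was called for 7310 genes, 3703 higher and 3607 lower. Over 697 induced genes the median was 1.18 in WT and 1.33 in ATF6_KO, with a median interaction of 0.13 (SD 0.034), 72 lower and 66 higher. The count rose to 1459 without ATF6_KO tunicamycin replicate 3, in which mitochondrial genes took 3.13% of counts. It dropped to 317, 338 and 331 without WT DMSO replicates 1, 2 and 3, to 327 without WT tunicamycin replicate 3, and to 310, 322 and 321 without ATF6_KO DMSO replicates 1, 2 and 3.

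In DMSO, ATF6_KO had carbonic anhydrase CA2 at 0.792 ± 0.0819 CPM against 18.4 ± 0.67 in WT (log2 -4.53, adjusted p = 1.38e-11, edgeR, Benjamini-Hochberg). The tyrosine kinase SYK was at 0.8 against 11.4 CPM, STK26 at -2.44 and RNF213 at -2.23. The serotonin receptor HTR7 was higher by 1.55, the pseudogenes DUXAP10 and DUXAP9 by 2.02 and 1.91, and AOPEP by 1.60. Of 18 hypoxia genes 10 were lower, 11 over the list alone (camera adjusted p = 5.1e-14), with the glucose transporter SLC2A3 at -2.14, and adjusted p = 0.0765 with an estimated correlation. ER translocation genes were higher in 11 of 20 cases, 16 over the list alone, with adjusted p = 0.0765 with an estimated correlation. In all 2749 genes were called, 1266 higher and 1483 lower, and 230 and 1134 on TPM, but 1725 and 1325 with the DESeq2 test. The count was 4723 without ATF6_KO tunicamycin replicate 3, 1778, 1792 and 1801 without WT DMSO replicates 1, 2 and 3, and 1714, 1732 and 1620 without ATF6_KO DMSO replicates 1, 2 and 3. No DMSO list call of ATF6_KO held with an estimated correlation.

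XBP1_KO asked the same of the factor made from IRE1-spliced XBP1 RNA. DNAJB9, an ER co-chaperone, rose from 5.29 to 8.3 CPM in XBP1_KO and from 9.12 to 96.6 in WT, an interaction of -2.76 ± 0.12 (adjusted p = 1.78e-07, edgeR, Benjamini-Hochberg). FICD, which modifies HSPA5, had -2.64 ± 0.15, the mannose-activating enzyme GMPPB -1.80 and the glutaredoxin GLRX -1.78. CCNP had -2.19 and MSTO2P -1.91. Of 20 genes of ER translocation and signal peptide processing 14 had a lower response, 19 adjusted over the list alone (median -0.573, camera adjusted p = 1.61e-38), with SEC61B at -1.16 and SSR2 at -1.02. Of 16 genes of ER-associated degradation 10 did, 11 over the list alone (median -0.729, camera adjusted p = 1.8e-37), with EDEM1 at -1.42 and SYVN1 at -1.19.

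Of 23 genes of ER to Golgi transport 15 had a lower response in XBP1_KO, 20 over the list alone (camera adjusted p = 3.84e-36), with the COPII coat gene SEC24D at -1.72. Of 25 genes of N-glycosylation 11 did, 17 over the list alone (camera adjusted p = 4.57e-26), with PGM3 of hexosamine synthesis at -1.28. Of 18 chaperones 10 did, 13 lower and 1 higher over the list alone (median -0.365, camera adjusted p = 2.42e-28), with ERO1B at -1.64. Heat shock genes had 2 of 13 lower, 3 over the list alone (camera adjusted p = 7.74e-05). Stress effectors went the other way, with 2 of 13 higher, 7 over the list alone (camera adjusted p = 5.94e-06), and DDIT4 at 1.07 ± 0.13. These 7 calls held with an estimated correlation. ARRDC4 had 0.97, PLEKHH2 0.87, PTPDC1 0.86, the cell cycle inhibitor CDKN2B 0.84 and JUN 0.82. The UPR sensors and transcription factors had a median of 0.004, -0.004 with no filter, a mean of -0.196 and a test downward, with 3 of 12 lower and adjusted p = 0.0613 with an estimated correlation; PERK's gene EIF2AK3 had -1.39. The other targeted genes were not called: ATF4 had -0.41, ATF6 0.21, NFIL3 0.18, DDIT3 0.09 and CEBPB 0.00. ATF4 was called with the DESeq2 test (-0.41), with no filter (-0.41), on all 24 libraries (-0.40), without XBP1_KO DMSO replicate 1 (-0.48) or 2 (-0.29), and without the libraries that stand apart (-0.32). PLEKHH2 was no longer called on TPM or without any 1 of 3 single libraries.

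edgeR with the Benjamini-Hochberg method called 344 of 16198 interactions in XBP1_KO, 53 higher and 291 lower, and the response for 6292 genes, 3116 higher and 3176 lower. Over 683 induced genes the median log2 change was 1.195 in WT and 1.112 in XBP1_KO. The median interaction was -0.006 (SD between library medians 0.044) and 0.032 on TPM, with 101 genes lower and 15 higher. The count of interactions was 534 without XBP1_KO DMSO replicate 1 and 563 without replicate 2, which stood apart. It also moved by more than 1.5 times on TPM, with the DESeq2 test, with no filter and without the libraries that stand apart. In DMSO 1991 genes were called, 743 higher and 1248 lower, and 156 and 1048 on TPM, or 1310 in all without WT DMSO replicate 2. SYK was at 0.0643 CPM against 11.4 in WT, and the epithelial membrane protein MAL2 at 11 ± 0.575 against 187 ± 7.16 (log2 -4.09, adjusted p = 3.39e-13, edgeR, Benjamini-Hochberg). MBNL3 and UCA1 were at -3.64 and -3.32. CSTA, FAT4 and VSNL1 were higher by 1.92, 1.62 and 1.56, and the nuclear receptor NR2F1 and the growth factor BMP4 by 1.49 each. Of 9 mesenchymal markers 5 were higher and 2 lower, 6 and 2 over the list alone (camera adjusted p = 1.34e-04), with VIM at 1.47, and adjusted p = 0.0568 with an estimated correlation. FAT4 was not called on TPM. Of 18 hypoxia genes 7 were lower, 9 over the list alone, with adjusted p = 0.194 with an estimated correlation. Of 18 chaperones 8 were lower, 9 over the list alone, with adjusted p = 0.213 with an estimated correlation. CDH1, the epithelial cadherin, stood at 11.3 CPM against 37.1.

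The 3 lines of set 2 were compared with each other to place each gene group without the WT libraries. Against ATF6_KO, ATF4_KO had a lower response of DDIT4 by -4.51 ± 0.20, of CHAC1 by -4.54, of SESN2 by -3.93, of TRIB3 by -3.51 and of SLFN5 by -3.30. FAM222A, RTN4RL1, SDF2L1 and MTCL1 had a higher response by 1.71, 1.65, 1.31 and 1.28. Of 18 chaperones 10 had a higher response, 13 over the list alone (camera adjusted p = 9.42e-13), and of 17 immediate early genes 8 a lower one, 13 over the list alone (camera adjusted p = 8.06e-17). Against XBP1_KO, ATF4_KO had a lower response of CHAC1 by -4.94, of B3GALT5 by -3.37 and of 11 of 13 stress effectors, 12 over the list alone (camera adjusted p = 2.14e-121). It had a higher response of DNAJB9 by 2.06 ± 0.13, FICD by 1.98 and GMPPB by 1.70, and of 8 of 20 genes of ER translocation, 12 over the list alone (camera adjusted p = 2.54e-07). ATF6_KO against XBP1_KO had HSPA5 at -1.37 ± 0.11 and HSP90B1 at -1.14, but DNAJB9 at 2.13 and HBEGF at 1.52. Its translocation genes had a higher response in 5 of 20 cases, 12 over the list alone (camera adjusted p = 7.49e-17), and its immediate early genes in 5 of 17 cases, 14 over the list alone (camera adjusted p = 1.06e-17). These list calls held with an estimated correlation. Its chaperones were lower in 6 of 18 cases and higher in 1, 9 and 3 over the list alone, with adjusted p = 0.0764 with an estimated correlation.

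ATF4_KO against ATF6_KO gave 1793 of 16011 genes called by edgeR with the Benjamini-Hochberg method, 831 higher and 962 lower, or 2887 without ATF6_KO tunicamycin replicate 3. ATF4_KO against XBP1_KO gave 1527 of 15911, 770 higher and 757 lower, and 655 and 371 on TPM. It gave 993, 995 and 1013 without ATF4_KO DMSO replicates 1, 2 and 3 and 994 without XBP1_KO tunicamycin replicate 2. ATF6_KO against XBP1_KO gave 177 of 15976, 136 higher and 41 lower. It gave 87, 76 and 75 without ATF6_KO DMSO replicates 1, 2 and 3, 108 without ATF6_KO tunicamycin replicate 2, 112 without XBP1_KO DMSO replicate 3, and 96, 84 and 83 without XBP1_KO tunicamycin replicates 1, 2 and 3.

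**Figure D3:**
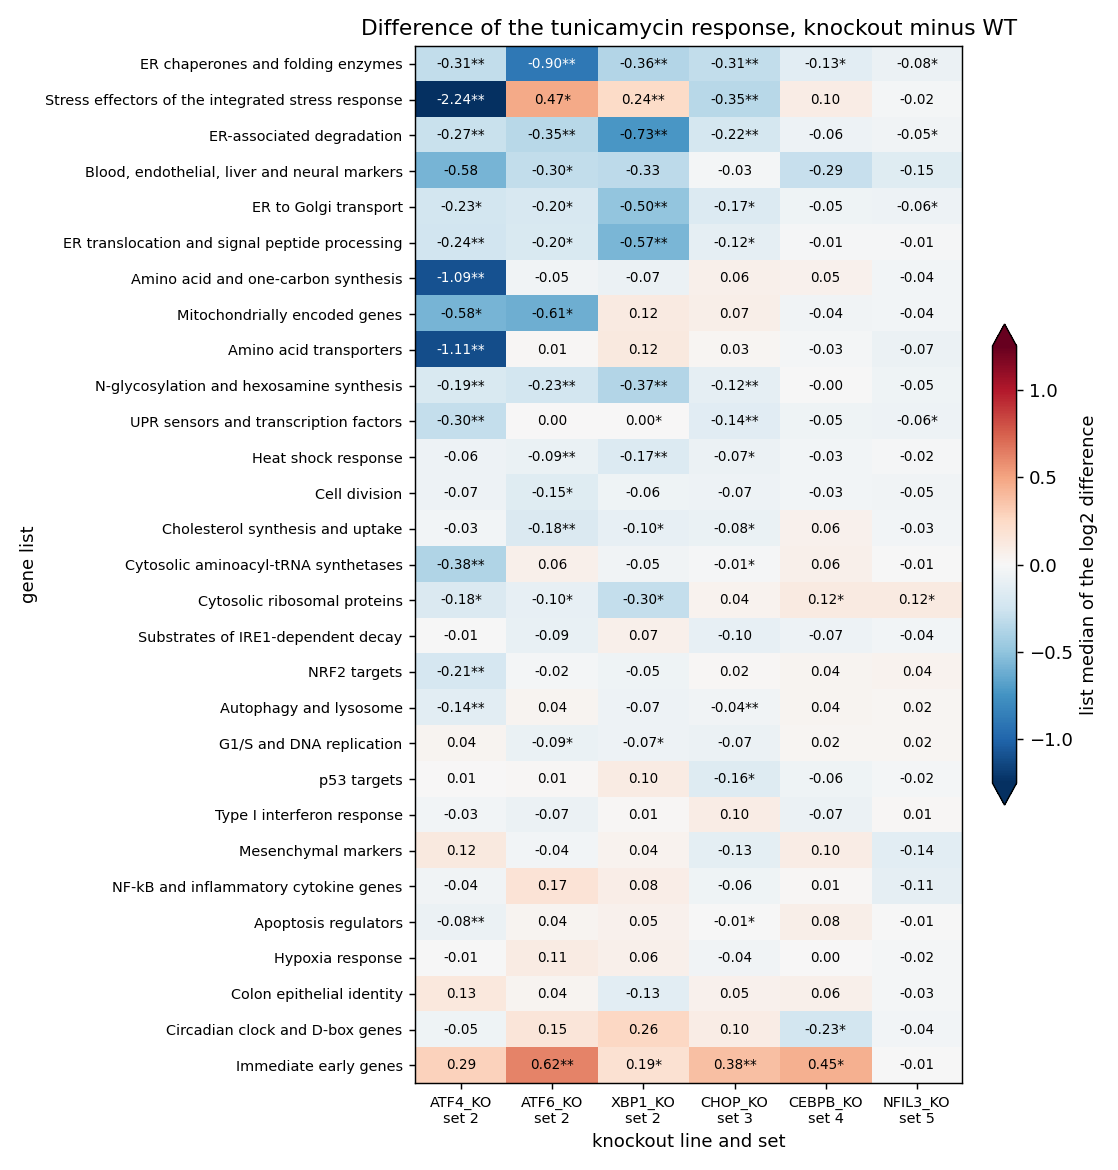
Median log2 difference of the tunicamycin response, knockout minus WT, of each gene list (vertical) in each knockout line (horizontal), with 1 star where camera called it and 2 where the call held with an estimated correlation. Stress effectors were at -2.24 in ATF4_KO, chaperones at -0.898 in ATF6_KO and ER-associated degradation at -0.729 in XBP1_KO; on TPM the starred medians turned positive for 4 lists in ATF4_KO (apoptosis, autophagy, N-glycosylation and NRF2), for 5 in ATF6_KO (blood and other markers, ribosomal proteins, ER translocation, G1/S and heat shock) and for 2 in XBP1_KO (cholesterol and G1/S), and with no filter the sign changed for UPR factors in XBP1_KO and apoptosis in CHOP_KO.

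CHOP_KO asked how the response differed in the line without the stress transcription factor CHOP. Its WT libraries, those of set 3, differed in DMSO from the WT of other sets, with values given below. NIBAN1, a stress-induced regulator of translation, rose from 0.505 to 1.11 CPM in CHOP_KO and from 1.28 to 18.6 in WT, an interaction of -2.77 ± 0.34 (adjusted p = 1.38e-05, edgeR, Benjamini-Hochberg). SLFN5 had -2.20 ± 0.16, ATF5, a bZIP factor of the stress response, -1.69 ± 0.07, AKNA -1.69, the selenophosphate synthetase SEPHS2 -1.67, GTPBP2 -1.65 and SGTB -1.64. CHAC1 went the other way, to 146 ± 5.33 CPM in CHOP_KO against 70 ± 5.39 in WT, an interaction of 1.24 ± 0.15. The protease gene PRSS8 had 1.20, RGS2 1.17 and CDKN2B 1.05. Stress effectors were divided, with 7 of 14 lower and 3 higher by both adjustments (camera adjusted p = 5.37e-10).

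Of 18 chaperones 13 had a lower response in CHOP_KO, 16 adjusted over the list alone (median -0.309, camera adjusted p = 6.61e-30), with HSPA5 at -0.65. Of 16 genes of ER-associated degradation 7 did, 11 over the list alone (camera adjusted p = 8.5e-10), with SEL1L at -1.08. Of 12 UPR sensors and transcription factors 4 did by both adjustments (camera adjusted p = 1.48e-09): NFIL3 had -0.97, ATF6 -0.79, the gene of IRE1, ERN1, -0.75 and CEBPB -0.40. ATF4 had -0.10 and XBP1 -0.08, not called. N-glycosylation had 3 of 25 lower, 6 lower and 1 higher over the list alone (camera adjusted p = 3.11e-05), with GFPT1 at -1.03. Immediate early genes had a higher response in 8 of 17 cases and a lower one in 1, 10 and 1 over the list alone (camera adjusted p = 2.57e-14), with MYC at 0.94. Autophagy had 2 of 18 lower and 1 higher (camera adjusted p = 0.00244). These calls held with an estimated correlation. On TPM the gene calls of ERN1 and CDKN2B ended.

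edgeR with the Benjamini-Hochberg method called 761 of 15401 interactions in CHOP_KO, 376 higher and 385 lower, and 130 and 219 on TPM. The response was called for 7585 genes, 3865 higher and 3720 lower, and 2244 and 4109 on TPM. Over 576 induced genes the median was 1.45 in WT and 1.22 in CHOP_KO. The median interaction was -0.249 (SD 0.026), with 153 lower and 22 higher. In DMSO 1295 genes were called, 489 higher and 806 lower, and 860 without WT DMSO replicate 1. LMAN1, a cargo receptor from the ER to the Golgi, was at 6.48 ± 0.553 CPM against 41.4 ± 0.19 (log2 -2.67, adjusted p = 5.05e-16, edgeR, Benjamini-Hochberg). RGS2 was at -2.03, PPP1R14C at -1.67, keratin 7 (KRT7) at -1.62 and CORO1A at -1.47. SLC16A6, HTR7, NR2F1 and CSTA were higher by 1.29, 1.23, 1.04 and 0.92.

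CEBPB_KO asked the same of C/EBP beta, with the RNA values of its gene given above. B3GALT5, a glycosyltransferase, rose from 1.66 to 2.39 CPM in CEBPB_KO and from 3.82 to 26.2 in WT, an interaction of -2.25 ± 0.21 (adjusted p = 1.19e-05, edgeR, Benjamini-Hochberg). MYCL had -1.84 ± 0.17, AAK1 -1.48, KIF21B -1.29, the netrin receptor UNC5B -1.16, RGS3 -1.12 and SLFN5 -1.10. RGS2, a regulator of G protein signalling, had 1.53 ± 0.18, and KRTAP2-3, ZNF697, DUSP8 and ARTN had 1.02, 0.87, 0.81 and 0.80. XBP1 had 0.27, called, whereas DDIT3 had 0.30, ATF4 0.18, ATF6 -0.15 and NFIL3 0.05. The level of NFIL3 was 13.9 CPM in CEBPB_KO against 18.2 in WT with DMSO, and 44.4 against 56 with tunicamycin. On TPM the calls of AAK1, KIF21B, DUSP8 and XBP1 ended, that of XBP1 also without any 1 of 8 single libraries, and ATF4 was called without WT DMSO replicate 3 (0.22). Immediate early genes had a higher response in 9 of 17 cases and a lower one in 1, 11 and 1 over the list alone (camera adjusted p = 9.55e-19), with JUNB at 0.66, and adjusted p = 0.0533 with an estimated correlation. Chaperones had 5 of 18 lower, 9 over the list alone, with adjusted p = 0.0649 with an estimated correlation. No interaction list call of CEBPB_KO or NFIL3_KO held with an estimated correlation.

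edgeR with the Benjamini-Hochberg method called 430 of 15465 interactions in CEBPB_KO, 197 higher and 233 lower, and the response for 8235 genes, 4115 higher and 4120 lower, and 2317 and 4824 on TPM. Over 586 induced genes the median interaction was -0.094 (SD 0.035), with 73 lower and 28 higher. The count was 879 without WT DMSO replicate 3, 276 and 257 without WT tunicamycin replicates 1 and 2, and 282 and 278 without CEBPB_KO tunicamycin replicates 1 and 3. In DMSO 2634 genes were called, 1166 higher and 1468 lower, and 379 and 929 on TPM. KRT7 was at 1.62 ± 0.471 CPM against 36.8 ± 2.07 (log2 -4.50, adjusted p = 2.07e-13, edgeR, Benjamini-Hochberg). The lipase MGLL was at -3.08, GRIN2B at -2.80 and SEMA3A at -2.75, and KRT7, MGLL and SEMA3A were lower in CHOP_KO and NFIL3_KO too. ZNF804A, VGF, S100A14 and NDRG1 were higher by 1.79, 1.46, 1.44 and 1.31. Of 15 circadian clock and D-box genes 11 were lower and 2 higher by both adjustments (camera adjusted p = 4.57e-16), with the clock repressors CRY1 at -1.58 and PER2 at -1.50. Of 8 mesenchymal markers 6 were lower by both adjustments (camera adjusted p = 6.31e-05), with VIM at -1.81. Both calls held with an estimated correlation.

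NFIL3_KO asked the same of NFIL3. edgeR with the Benjamini-Hochberg method called 19 of 15894 interactions, 10 higher and 9 lower, and 1319 at an unadjusted p under 0.05. The response of SLC7A11 was lower by -0.62 ± 0.06 (adjusted p = 0.00129), from 72.4 to 539 CPM in NFIL3_KO and from 39 to 445 in WT. SEC24D had -0.53 ± 0.06, CORO2A -0.56, ATP13A2 -0.47, HMGCS1 -0.45, PLAUR -0.42, IFRD1 -0.39 and HERPUD1 -0.32. AMOTL1 had 0.91 ± 0.10, CPEB3 0.79, SLC2A3 0.75, AUH 0.51, MINDY2 0.49 and the stress factor ATF3 0.48. The other targeted genes lay between -0.08 for CEBPB and 0.10 for XBP1, and none was called. ER to Golgi transport had 1 of 23 genes lower, 7 over the list alone (camera adjusted p = 8.01e-06), with adjusted p = 0.147 with an estimated correlation. The response was called for 8472 genes, 4353 higher and 4119 lower, and 2653 and 4439 on TPM. Over 628 induced genes the median interaction was -0.079 (SD 0.036), with 4 lower and 2 higher.

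The 19 interactions of NFIL3_KO split as 2 higher and 4 lower on TPM, 69 and 143 with no filter, and 20 and 41 with the DESeq2 test. On TPM AUH and PLAUR alone of the 14 genes named above were still called, but calls also ended when single libraries were left out: 7 such libraries for AUH and HMGCS1, 10 for PLAUR, ATF3, ATP13A2, CPEB3 and HERPUD1, and 11 for CORO2A and IFRD1. Without WT DMSO replicate 2, which stood apart, 61 were called. Without WT tunicamycin replicates 1, 2 and 3 the count was 7, 8 and 10, without NFIL3_KO DMSO replicates 1, 2 and 3 it was 9, 7 and 6, and without any 1 of the NFIL3_KO tunicamycin replicates it was 6.

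In DMSO 3308 genes differed between NFIL3_KO and WT, 1730 higher and 1578 lower, and 1019 and 502 on TPM, with 2203 and 2122 without NFIL3_KO DMSO replicates 1 and 3. Cholesterol synthesis and uptake was higher: 16 of 24 genes were called, 18 adjusted over the list alone (median 0.353, camera adjusted p = 3.23e-18), a call that held with an estimated correlation. INSIG1 was higher by 0.71 and STARD4 by 0.61. The homeobox gene MSX2, DIRAS3, VSNL1 and the matrix proteoglycan VCAN were higher by 1.62, 1.41, 1.39 and 1.25. ZNF22 was lower at -3.49, TNFSF18 at -2.61, the matrix protein THBS1 at -2.47 and TXLNG at -2.20 ± 0.05 (adjusted p = 3.19e-13, edgeR, Benjamini-Hochberg). Ribosomal proteins were lower in 10 of 24 cases, 19 over the list alone, with adjusted p = 0.902 with an estimated correlation.

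**Figure D4:**
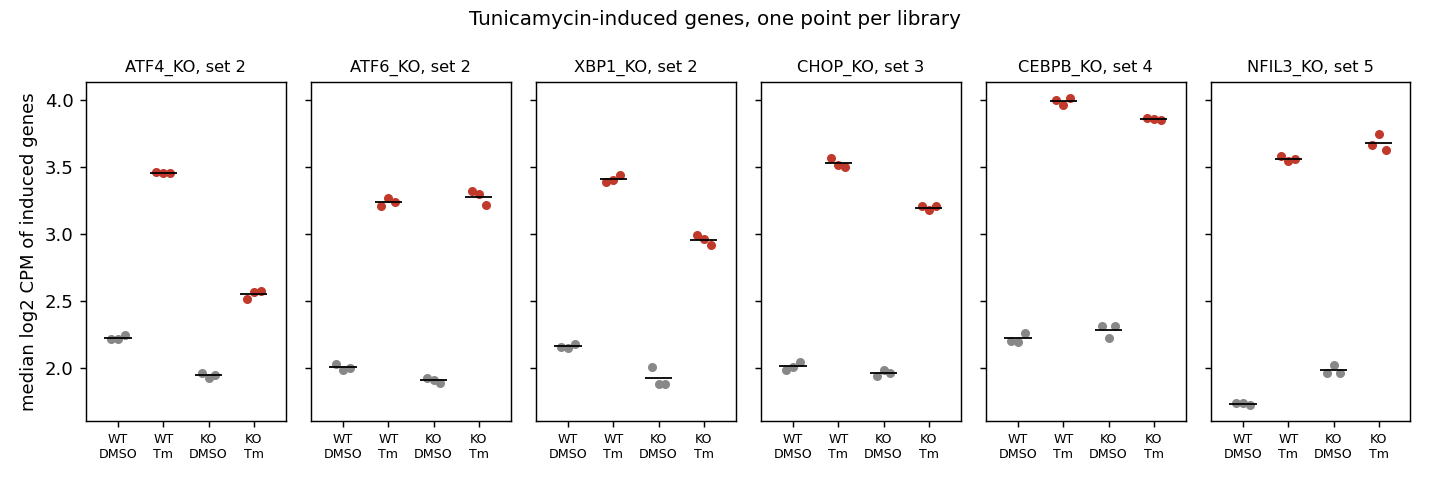
Median log2 CPM of the tunicamycin-induced genes in each library (points; lines are means of 3), for WT and knockout (KO) in DMSO and tunicamycin (Tm). The median interaction of these genes was -0.625 in ATF4_KO (nearer to 0 on TPM), -0.249 in CHOP_KO, -0.094 in CEBPB_KO, -0.079 in NFIL3_KO, -0.006 in XBP1_KO (0.032 on TPM) and 0.13 in ATF6_KO. These are medians over genes, not differences of the plotted library medians, which rose less in XBP1_KO than in its WT. In that panel WT lay at 2.15 to 2.183 with DMSO and 3.387 to 3.444 with tunicamycin. XBP1_KO lay at 1.878 to 2.006 and 2.92 to 2.995.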

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

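The tunicamycin response differed between groups of libraries under the same contrast, by an interaction test of edgeR, and this is what brought each of the following results here. The interaction with the knockout was called for 1833 genes in ATF4_KO, 530 in ATF6_KO, 344 in XBP1_KO, 761 in CHOP_KO, 430 in CEBPB_KO and 19 in NFIL3_KO. The response differed between knockout lines for 1793 genes (ATF4_KO against ATF6_KO), 1527 (ATF4_KO against XBP1_KO) and 177 (ATF6_KO against XBP1_KO). It differed between the 5 sets of WT libraries for 4350 genes, 2748 with the same sign in all sets and 1602 with both signs. The tests of the even splits, and the comparison of immediate early genes between ATF6_KO and XBP1_KO, were chosen after the results were seen. The predictions of the other tests were written before their results, but the limit that sets libraries apart, on which some of them rest, was chosen after the data were seen.

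Splits of the same libraries into other groups gave 1 of 30 at or above the real count for the WT response (highest other 2, real 11503) and 1 of 30 for the difference between sets (highest other 1, real 4350). For each single line or set, in tunicamycin against DMSO or against WT in DMSO, the splits were too few, 1 of 10, the real one, with at most 1 gene in any other. All of these splits mix the groups compared, so the real effect entered the spread. Low counts were likely in advance, and these splits cannot decide whether the real counts arose by chance. For the interactions of a knockout with treatment, some of the 23 splits that divide the lines unevenly between treatments called several times the real count. Of those 23, 1 reached it for ATF4_KO against ATF6_KO, 2 for ATF6_KO and 4 for each of the other 7. The numbers of 40 splits at or above the real one were 5 for ATF4_KO (highest other 7472, real 1833), 3 for ATF6_KO (5140, real 530), 5 for XBP1_KO (4051, real 344), 5 for CHOP_KO (3455, real 761), 5 for CEBPB_KO (4735, real 430) and 5 for NFIL3_KO (5226, real 19). They were 2 for ATF4_KO against ATF6_KO (6535, real 1793), 5 for ATF4_KO against XBP1_KO (6722, real 1527) and 5 for ATF6_KO against XBP1_KO (4177, real 177). The highest counts point to sample structure, as uneven splits carry the difference between lines in DMSO. Among even splits, which part the lines alike in both treatments, 1 of 30 reached the real count in each of the 9, and any other called at most 1 gene. Apart from the real split, each of their groups mixes libraries of both lines, so the difference between lines enters the spread. Few calls were thus likely in advance, and the even splits cannot decide whether the real counts arose by chance.

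For the median interaction of the induced genes, 5 of 40 splits reached the real size in ATF4_KO (highest other 0.816, real 0.625). It was 1 of 40 in ATF6_KO (0.098, real 0.13), CHOP_KO (0.236, real 0.249), CEBPB_KO (0.061, real 0.094) and NFIL3_KO (0.077, real 0.079), and 37 of 40 in XBP1_KO. Among even splits it was 1 of 30 in ATF4_KO (0.271), ATF6_KO (0.078), CHOP_KO (0.115), CEBPB_KO (0.063) and NFIL3_KO (0.045), and 27 of 30 in XBP1_KO, so the median of XBP1_KO did not stand out from its splits. Even splits mix the lines in each group and keep only part of a real difference. Smaller medians were thus likely in advance, and the even splits cannot decide for the other lines.

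In DMSO, 169 genes were lower than WT in CHOP_KO, CEBPB_KO and NFIL3_KO alike, lines of 3 sets with separate WT libraries, where 8 were expected from the separate counts, a ratio of 21.1, so a separate gene set for each deleted factor did not account for it; 53 genes were higher in all 3 (4.5 expected). A WT library that stood apart did not account for it, since 184 genes were shared without that library. Gene length did not either, with the shared genes at percentile 57.8 of the genes tested. In set 2, 125 of the 169 were called lower in ATF4_KO, 90 in ATF6_KO and 103 in XBP1_KO (74%, 53.3% and 60.9%, against 15.8%, 9.7% and 8% of all genes), with 12, 12 and 14 called higher, and named genes such as KRT7, MGLL, SEMA3A, RGS2, THBS1, SOX4, TRIB2, SLC2A3 and UCA1 were among the 169. A difference between the knockout lines and WT that does not depend on which factor was deleted could explain this; it was not tested further, and the labels do not state whether a line is 1 clone or what the WT cells were.

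Immediate early genes had a higher tunicamycin response in ATF6_KO. Without the libraries that stand apart 16 of the 17 members were called higher, so those libraries were not the cause. The list was also higher in ATF6_KO than in XBP1_KO, with a median of 0.517, a contrast without WT libraries. The same list was higher in CHOP_KO and CEBPB_KO in other sets, in CEBPB_KO with adjusted p = 0.0533 with an estimated correlation. Signalling that ATF6 or its targets restrain may be involved, but ATF6 was not the gene deleted in those 2 lines. A difference between knockout lines and WT that does not depend on the deleted factor may also contribute. No perturbation here tests either.

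Mitochondrially encoded genes had a lower median response in ATF4_KO (-0.58) and in ATF6_KO (-0.61), with no member called. Without the libraries that stand apart the medians were -0.014 in ATF4_KO, with 2 of 13 members called lower, and -0.001 in ATF6_KO, with none called. ATF6_KO tunicamycin replicate 3 had 3.13% of its counts in these genes and ATF4_KO tunicamycin replicate 1 had 3.73%. WT DMSO replicate 1 of set 2, left out of both comparisons, had 4.81%, against 7.46% and 7.41% in its replicates. The shift of the medians thus rested on the libraries that stand apart.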

How the results depend on the processing

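Of 765 alternative values of the counts, induced-gene medians and list tests, 661 stayed within 1.5 times or 1 SD of the main value, and 104 did not. Direction held for the induced-gene medians except that of XBP1_KO, which was 0.032 on TPM and 0.006 on all 24 libraries and without WT tunicamycin replicate 1 of set 2. For 257 named genes in comparisons, 5451 alternative values kept direction and side of the threshold, 141 lost the call, 13 gained it and 18 changed sign. The cause was not tested except where said. The TPM alternative had no further normalization between libraries, so a shift of the median of all genes enters its splits and list medians. Adding 1 before the log also shrinks the changes of genes with low TPM. Depth limits the genes of low count.

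On TPM with limma-trend the counts were 2035 between sets, 2566 for the response of ATF4_KO, and for the interactions 255 (ATF6_KO), 145 (XBP1_KO), 349 (CHOP_KO), 111 (CEBPB_KO) and 6 (NFIL3_KO). In DMSO they were 3147 (ATF4_KO), 1364 (ATF6_KO), 1204 (XBP1_KO), 571 (CHOP_KO), 1308 (CEBPB_KO) and 1521 (NFIL3_KO). They were 1062 for ATF4_KO against ATF6_KO and 72 for ATF6_KO against XBP1_KO, and the induced-gene medians were -0.329 (ATF4_KO) and -0.208 (CHOP_KO). With the DESeq2 test the interactions were 880 (ATF6_KO), 571 (XBP1_KO) and 61 (NFIL3_KO), and ATF6_KO against XBP1_KO 433. With no filter they were 587 (XBP1_KO), 1005 (CEBPB_KO) and 212 (NFIL3_KO), ATF6_KO against XBP1_KO 319, and the median of ATF6_KO 0.095. The fit on all 24 libraries of set 2 gave 567 for ATF6_KO against XBP1_KO. DESeq2 size factors moved no count beyond 1.5 times.

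Without the libraries that stand apart, the interactions were 3530 (ATF4_KO), 2030 (ATF6_KO), 789 (XBP1_KO; 241 higher and 548 lower) and 61 (NFIL3_KO; 18 and 43). The same run gave 4166 for ATF6_KO in DMSO, 4409 for ATF4_KO against ATF6_KO, 2986 for ATF4_KO against XBP1_KO and 906 for ATF6_KO against XBP1_KO (593 and 313). On all 24 libraries the interaction of XBP1_KO had 120 higher and 343 lower. With induced genes of log2 change 2 or more, the medians were -1.498 (ATF4_KO), 0.169 (ATF6_KO) and -0.501 (CHOP_KO). Chosen on the same set, which brings chance of the WT libraries in, they were -0.851 (ATF4_KO), 0.053 (ATF6_KO), -0.183 (XBP1_KO), -0.318 (CHOP_KO), -0.167 (CEBPB_KO) and -0.124 (NFIL3_KO). Of 638 list tests 273 were called, 155 with an estimated correlation and 364 with fry, none with another direction.

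Replicate numbers did not pair the libraries: the correlation of same-numbered libraries in set 2 ran from -0.761 to 0.619, and 49 of 168 correlated best with their own number (1 of 6, 9 of 36, 12 of 36 and 8 of 36 in sets 1, 3, 4 and 5). With the replicate number as a block, ATF6_KO against XBP1_KO gave 93 and the interaction of NFIL3_KO 8, and the other counts stayed within 1.5 times, such as 3227 for the difference between sets. Of the named genes, the calls of XBP1 in CEBPB_KO and of CORO2A, ATP13A2, PLAUR, IFRD1, HERPUD1, CPEB3 and AUH in NFIL3_KO ended under the block.

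Leaving out 1 library at a time, the interactions ran from 1229 to 2969 (ATF4_KO), 310 to 1459 (ATF6_KO), 235 to 563 (XBP1_KO), 541 to 823 (CHOP_KO), 257 to 879 (CEBPB_KO) and 6 to 61 (NFIL3_KO). In DMSO they ran from 3851 to 6403, 1620 to 4723, 1310 to 2694, 860 to 1529, 1841 to 2622 and 2122 to 3758 in the same order. The responses ran from 2965 to 5076, 6325 to 8261, 4998 to 6736, 6798 to 7585, 7502 to 8644 and 7608 to 9519. Between lines they ran from 1260 to 2887 (ATF4_KO against ATF6_KO), 993 to 1793 (ATF4_KO against XBP1_KO) and 75 to 240 (ATF6_KO against XBP1_KO). The WT response ran from 11416 to 11626 and the difference between sets from 3462 to 4799. The induced-gene medians ran from -0.688 to -0.608 (ATF4_KO), 0.111 to 0.157 (ATF6_KO), -0.033 to 0.006 (XBP1_KO), -0.277 to -0.231 (CHOP_KO), -0.111 to -0.074 (CEBPB_KO) and -0.093 to -0.065 (NFIL3_KO).

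The values that changed sign were those of targeted genes that were not called. XBP1 in ATF4_KO was 0.0289 on TPM. DDIT3 in ATF6_KO was 0.045 on TPM and 0.0194, 0.0106, 0.0254 and 0.0422 without single libraries, whose values ran from -0.137 to 0.0422. CEBPB in XBP1_KO was 0.15 on TPM, 0.00567 with the replicate block, 0.00875 on all 24 libraries, 0.151 without the libraries that stand apart, and 0.00885, 0.00922, 0.0058, 0.00619, 0.176 and 0.0357 without single libraries, whose values ran from -0.09148 to 0.176. NFIL3 in CEBPB_KO was -0.00593 on TPM and -0.0573 without 1 library, and single libraries left out gave -0.0573 to 0.121.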

Other observations

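Some genes linked the responses of lines from different sets. TNFRSF10B, the death receptor DR5, had a lower response in ATF4_KO (-1.77) and in CHOP_KO (-1.57). So did MAP1LC3B, the autophagosome protein LC3B (-2.11 and -1.06), and GFPT1 (-0.80 and -1.03). SLFN5, a member of the Schlafen family, had a lower response in CHOP_KO (-2.20) and CEBPB_KO (-1.10). RGS2, a brake on G protein signalling, was 8.58 CPM in CEBPB_KO with DMSO against 18.4 in WT, and with tunicamycin 12.5 against 9.32. In CHOP_KO, too, RGS2 was lower in DMSO (-2.03) and had a higher response (1.17), but it was also lower in DMSO in NFIL3_KO (-0.58), ATF6_KO (-0.38) and XBP1_KO (-0.52), and higher in ATF4_KO (0.60).

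B3GALT5, a glycosyltransferase, was 0.0515 CPM in CHOP_KO with DMSO and 0.011 with tunicamycin, against 1.5 and 7.19 in WT of set 3. In XBP1_KO it was 0.82 and 5.39 CPM, against 6.24 and 22.5 in WT of set 2. In WT libraries with DMSO, LMAN1 was 41.4 CPM in set 3, 131 in set 2, 117 in set 4 and 123 in set 5, and CLIC4 was 25.6 CPM in set 3 and 115, 103 and 126 in sets 2, 4 and 5. Targeted genes differed too: DDIT3 was 23.72 CPM in set 3 and 6.555 to 9.471 in the other sets. ATF4 was 586.3 against 292.6 to 405, and ATF6 24.2 against 42.25 to 56.49. XBP1 at 63.2 lay within the others, 54.92 to 69.22. CHOP_KO was compared with these WT libraries of set 3 only. What the sets are was not stated, and the libraries of set 3 also had the lowest mean effective gene lengths, so the cause was not tested.

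The test of the overlap of ATF4_KO and CHOP_KO was chosen before its result was seen, and the other overlaps are given as values. Genes with a lower tunicamycin response were shared by ATF4_KO and CHOP_KO, which have separate WT libraries: 218 against 23.1 expected from the separate counts, a ratio of 9.44. That was above the limit set in advance for overlap by chance. The expected number takes all genes tested as equally likely to be called. Genes called more readily in any line could also raise the overlap, and this test cannot exclude that. Genes with a higher response in both ATF4_KO and CHOP_KO numbered 116 against 22.6. Genes lower in ATF4_KO and higher in CHOP_KO numbered 38 against 22.5, and those higher in ATF4_KO and lower in CHOP_KO 1 against 23.2. Opposite directions were also uneven for ATF6_KO. Genes higher in ATF6_KO and lower in CHOP_KO numbered 23 against 7, and the reverse 0 against 6.4. DDIT3 itself had a lower response in ATF4_KO (-1.10), so part of what ATF4 controls may pass through CHOP. It still rose there, from 6.51 to 140 CPM, against 8.08 to 348 in WT. The overlap does not single out this path. The ratio for genes with a lower response was 10.3 for ATF6_KO with CHOP_KO, 9.86 for XBP1_KO with CHOP_KO and 19.5 for CHOP_KO with CEBPB_KO. Against a simple chain, CHAC1 had a lower response in ATF4_KO (-4.83) and a higher one in CHOP_KO (1.24), and a line without both factors would test this.

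Other overlaps across sets were also above the product of the separate counts. ATF4_KO and CEBPB_KO shared 107 genes with a lower response (13.8 expected), CHOP_KO and CEBPB_KO 117 (6 expected), ATF6_KO and CHOP_KO 68 (6.6 expected) and XBP1_KO and CHOP_KO 73 (7.4 expected). Genes with a higher response were shared by CHOP_KO and CEBPB_KO (79, 4.9 expected), ATF6_KO and CHOP_KO (56, 6.8 expected) and ATF6_KO and CEBPB_KO (51, 3.5 expected). Genes lower in ATF4_KO and higher in CEBPB_KO numbered 34 (11.6 expected).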
